A study of Mus musculus with 7 samples.

How the data were processed

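RNA from sorted β cells of mouse pancreatic islets was sequenced in 7 samples, 4 of the genotype Atf6fl/fl (WT) and 3 in which Atf6 had been deleted in β cells (KO). Per the labels, islets came from collagenase digestion, mice were 6 weeks old, and pups received tamoxifen at 1 mg/ml from postnatal day 1 to 3 to switch on Cre recombinase. The labels give this treatment for both genotypes and do not say whether WT mice carried the Cre transgene. Samples were grouped by the genotype in their labels, and each carries an animal number of its own. The number of 1 of the 4 WT animals lies among those of the KO animals, and the other WT numbers form an earlier series, so animal series and genotype overlap in part. No sequencing batch is given in the sources used here.

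The values analysed here are those of the authors' deposited table, a comparison of KO with WT for 15961 genes with Ensembl identifiers. It holds the authors' log2 fold change of KO over WT and the authors' mean log2 CPM, a read count scaled to library size, over the libraries. It also holds the authors' likelihood ratio, a score for each gene, with the p-value and the adjusted p-value that the authors derived from it. The submitters' processing notes name bcl2fastq 2.20, STAR 2.5.3a, RSEM 1.2.31, edgeR 3.16.15 and the genome build GRCm38.p5, without giving the role of each. The scaling, the filter on low counts and any covariates are not given in the sources used here. The p-value of every gene in the authors' deposited table equals the upper tail of the chi-square distribution with 1 degree of freedom at its likelihood ratio. The adjusted p-values fit a Benjamini-Hochberg adjustment over 16008 tests, of which 15961 genes were analysed here. The authors' marks of changed genes fall exactly on those with an adjusted p under 0.05.

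Values per library were not used here, so the depth of each sample is unknown and no spread between replicates could be computed. The quasi-likelihood fit planned for counts was replaced by the fallback fixed with it, in which fold changes, p-values and calls are taken from the authors' deposited table. The planned test of gene lists on the moderated statistics of that fit was run on the authors' likelihood ratios instead. An approximate standard error (SE) was computed for each gene as the size of its log2 fold change over the root of its likelihood ratio, and an approximate 95% interval as 1.96 such errors to either side. The likelihood ratio test does not carry the uncertainty of the dispersion estimate, and p-values from groups of 3 and 4 can be too small. The median likelihood ratio was 1.72 times that of the chi-square distribution, so a version with all ratios divided by this inflation factor was also computed. The median SE was 0.113 for the 4987 genes at a mean log2 CPM of 5 or more and 0.641 for the 2703 genes under 1, in log2 units. Coordinates and gene types were taken from the GENCODE M21 annotation of GRCm38, which held 15956 of the 15961 identifiers.

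Before the data were examined, 32 lists with 655 genes were fixed, covering the branches of the unfolded protein response, β cell identity and function, senescence, p53 targets, secreted factors, immune signalling, cell cycle, apoptosis, metabolism, markers of other cell types, dissociation and sex. Of these genes, 457 were measured. The 23 lists with at least 5 measured members were tested with the pre-ranked camera test of limma 3.58.1 in R 4.3.3, two-sided, with the signed root of the likelihood ratio as the statistic and a preset inter-gene correlation of 0.01. The p-values were adjusted by the Benjamini-Hochberg method over the lists. An estimated correlation needs values per library and was not computed. Some genes are on several lists. List counts are given at an adjusted p under 0.05 over all genes and, for comparison, adjusted over the list alone. Another 3 lists (estrogen receptor targets, growth hormone and prolactin targets, and ribosomal RNA repeat loci) were added after values had been seen.

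The rule for named genes was also fixed in advance. It takes Atf6, Atf6b, Cdkn1a, Lif, Ins1 and Ins2 always, and the 10 largest rises and 10 largest falls among changed genes with a mean log2 CPM of at least 1 and a symbol that is not a predicted gene. In each list it takes up to 4 changed members with the smallest p, or, where none changed, 1 or 2 with the smallest p as values. Its further condition, that WT and KO values do not overlap, needs values per library and was not applied. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

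The steps were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and tested on simulated data. The simulation drew independent standard normal statistics and added shifts scaled by the approximate SE of each gene. Over 15961 genes, 62.0% of 200 genes changed by 1.00 on the log2 scale were recovered and 3.13% of the calls were false. At a change of 0.50 on the log2 scale, 21.5% of 200 genes were recovered and 4.44% of the calls were false. Of 250 unchanged lists of 25 genes, 2.4% reached a p under 0.05 in the list test. The simulation held no counts, replicates, inflation of the ratios or correlation between genes, so these rates need not hold for the real comparison. The alternatives were a 2-fold minimum, a mean of at least 1 CPM, leaving out the 20 most abundant genes, division by the inflation factor, an adjusted p under 0.01, and, for lists, ranks or fold changes as the statistic, a correlation of 0.05 and Fisher's exact test on the changed genes.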

Results

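The transcriptomes of β cells sorted from the islets of 6-week-old mice were compared between 4 Atf6fl/fl animals (WT) and 3 animals with β cell deletion of Atf6 (KO). ATF6 is a transmembrane protein of the endoplasmic reticulum (ER) that is cleaved under ER stress and then acts as a transcription factor for chaperone genes. The series title places the comparison in work on early senescence, secreted factors of β cells and type 1 diabetes. The question addressed was which genes differ in expression in β cells without Atf6. Fold changes and adjusted p-values are those of the authors' deposited table, from its likelihood ratio test with Benjamini-Hochberg adjustment, and are given as log2 of KO over WT. Depth per sample is unknown, and the approximate intervals were derived from the same ratios.

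Atf6 itself was lower in KO β cells. The authors' deposited table gives a log2 fold change of -1.16 (approximate 95% interval -1.34 to -0.98), a level 55.3% below that of WT, at a mean of 168 CPM and an adjusted p of 1.91e-32. Atf6 lies on chromosome 1 at 170704674 to 170867771 (GRCm38). The value covers the whole gene, so reads from exons outside the deleted part count towards it. How complete the deletion was cannot be read from this value. For Atf6b, the paralog of Atf6, the authors' deposited table gives -0.23 with an adjusted p of 0.377.

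The KO β cells had higher expression of p53 target genes, with Cdkn1a, Eda2r and Phlda3 among them, and lower expression of genes of mature β cells, with Slc2a2, Ucn3 and Mafa among them. Insulin transcripts were not called changed. Of 15961 genes in the authors' deposited table, 698 changed at an adjusted p under 0.05, of which 394 rose and 304 fell in KO. These are 4.37% of the genes, and 56.4% of the changed genes were higher. The median fold of the higher genes was 1.81 and that of the lower genes 0.685 in the authors' deposited table, and 638 of the changed genes were protein-coding. At a change of at least 2-fold, 151 genes rose and 58 fell in the authors' deposited table. When the ratios were divided by their inflation factor of 1.72, 115 genes rose and 84 fell.

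Genes activated by p53, the transcription factor of the DNA damage response, rose as a group in KO β cells. Of 26 measured members 13 rose, 0 fell and 13 did not pass, and adjusted over the list alone 15 rose and 1 fell. The median log2 fold change was 0.68 and the list passed the camera test (adjusted p = 2.24e-39). In the authors' deposited table, Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.61 on the log2 scale (interval 1.39 to 1.84, a 3.06-fold change, mean 117 CPM, adjusted p = 3.78e-41). Ccng1, the gene of cyclin G1, rose by 1.55 in the authors' deposited table (adjusted p = 1.49e-29). Eda2r, a receptor of the tumor necrosis factor receptor family, rose by 3.07 and Phlda3, an inhibitor of Akt signalling, by 2.46 in the authors' deposited table, at means of 8.41 and 9.66 CPM. Trp53, the gene of p53, had a log2 fold change of 0.21 and an adjusted p of 0.686 in the authors' deposited table, a gene chosen after its values were seen. Sst, Pyy and Rbp4, 3 of 9 measured markers of delta and PP cells, were also higher in KO, though their list did not pass as a group. Their values are given with the other marker lists.

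The list of senescence genes and cyclin-dependent kinase inhibitors did not pass the camera test as a group (median 0.01, adjusted p = 0.0897). Of 19 measured members 2 rose, 0 fell and 17 did not pass, and adjusted over the list alone 2 rose and 1 fell. The 2 genes, Cdkn1a and the death receptor gene Tnfrsf10b, are also on the p53 list. Tnfrsf10b rose by 1.76 on the log2 scale in the authors' deposited table (adjusted p = 6.88e-06). Among regulators of apoptosis, 2 of 21 measured genes rose, 0 fell and 19 did not pass, with 3 and 0 adjusted over the list alone, and the list did not pass (median 0.06, adjusted p = 0.131). Bbc3, which encodes the BH3-only protein PUMA, rose by 0.94 and the pore-forming effector gene Bax by 0.65 in the authors' deposited table, with adjusted p-values of 2.24e-06 and 8.05e-06. Both are p53 list members too.

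Genes of β cell identity and function fell as a group in KO. Of 25 measured members 0 rose, 7 fell and 18 did not pass, and adjusted over the list alone 0 rose and 12 fell, with a median log2 fold change of -0.24 (camera adjusted p = 4.68e-10). In the authors' deposited table, the glucose transporter gene Slc2a2 had a log2 fold change of -0.97 (interval -1.26 to -0.69, adjusted p = 8.42e-09) and Ucn3, a peptide hormone of mature β cells, one of -0.90 (adjusted p = 1.76e-06). Mafa and Pdx1, transcription factors that drive insulin gene expression, stood at -0.83 and -0.52 in the authors' deposited table, with adjusted p-values of 9.62e-05 and 0.000155. The other 3 lower members were Prlr, the prolactin receptor gene, chosen after its values were seen, Sytl4 and Slc30a8. Prlr stood at -0.67 and Sytl4, whose product granuphilin docks insulin granules, at -0.56 in the authors' deposited table. Ins1 had -0.08 (interval -0.71 to 0.56, adjusted p = 0.955) and Ins2 -0.21 (interval -0.93 to 0.51, adjusted p = 0.86) in the authors' deposited table, so changes of up to these bounds are not excluded. Of 9 measured delta and PP cell markers 3, Sst, Pyy and Rbp4, were higher in the same comparison, though their list did not pass as a group.

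The lists closest to β cell identity did not pass as groups. Among genes of immature β cells or normally silent in them, 1 of 12 measured rose, 1 fell and 10 did not pass, with 1 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 0.216). Aldh1a3, an aldehyde dehydrogenase gene induced in dedifferentiating β cells, rose by 2.44 in the authors' deposited table, at a mean of only 0.904 CPM (adjusted p = 0.0162). Npy, a neuropeptide gene expressed in immature β cells, had -1.60 in the authors' deposited table (adjusted p = 4.9e-06). Of 13 measured type 1 diabetes autoantigen genes 0 rose, 1 fell and 12 did not pass, with 0 and 2 adjusted over the list alone (median -0.09, adjusted p = 0.108). The gene that fell was Slc30a8, the zinc transporter of insulin granules, at -0.51 in the authors' deposited table (adjusted p = 0.00601). Of 28 insulin granule and exocytosis genes 0 rose, 1 fell (Sytl4) and 27 did not pass, with 0 and 1 adjusted over the list alone (median 0.01, adjusted p = 0.902). With the ratios divided by their inflation factor, the adjusted p of Aldh1a3 was 0.259 and that of Slc30a8 was 0.164, which ended both calls.

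Targets of ATF6, chaperones and folding enzymes of the ER, were lower as a group. Of 24 measured members 0 rose, 3 fell and 21 did not pass, and adjusted over the list alone 0 rose and 6 fell, with a median log2 fold change of -0.17 (camera adjusted p = 2.45e-05). In the authors' deposited table, Creld2, a secreted ER stress protein gene, had -0.84 (adjusted p = 6.83e-09), Sdf2l1, a component of ER chaperone complexes, -0.67 (adjusted p = 0.0125), and Herpud1, an ER-associated degradation gene, -0.32 (adjusted p = 0.0326). Hspa5, the gene of the main ER chaperone BiP, had -0.57 (interval -0.96 to -0.18, adjusted p = 0.0815) in the authors' deposited table, chosen after its values were seen, and did not pass. The delta and PP cell markers Sst, Pyy and Rbp4, 3 of 9 measured on a list that did not pass, were higher in the same comparison as the ATF6 list was lower. With fold changes as the statistic the list's adjusted p was 0.0716, and with Fisher's exact test it was 0.271, which ended the call. With the ratios divided by their inflation factor, the calls of Sdf2l1 and Herpud1 ended, with adjusted p-values of 0.231 and 0.362.

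**Figure D1:**
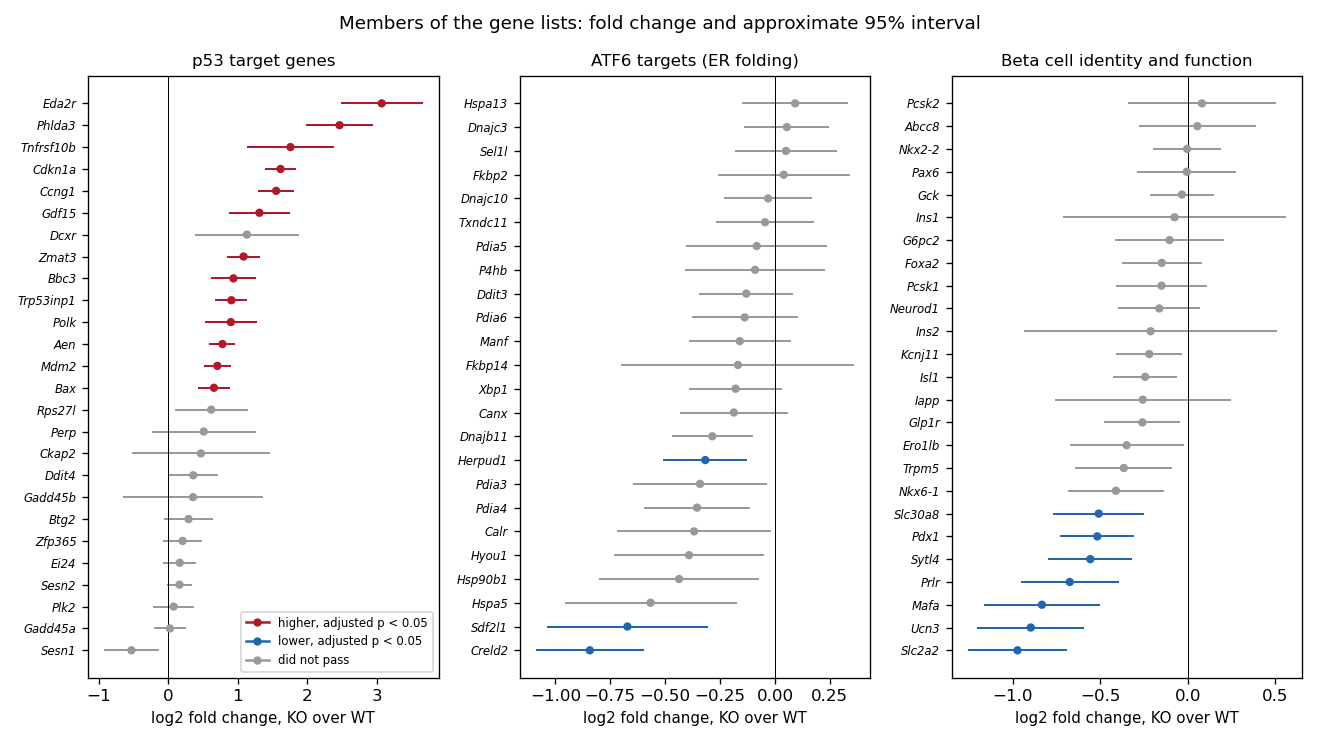
Log2 fold change of KO over WT (x axis) for each measured member of the p53 target, ATF6 target and β cell identity lists, from the authors' deposited table, with approximate 95% intervals as bars. Red marks members that were higher and blue members that were lower at an adjusted p under 0.05, and grey the rest: 13 p53 targets are red, and 3 ATF6 targets and 7 identity genes are blue.

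The other branches of the unfolded protein response did not pass as groups. Of 28 PERK-ATF4 pathway genes 2 rose, 3 fell and 23 did not pass, with 2 and 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.146). Nupr1, a stress-induced nuclear protein gene, rose by 1.24 in the authors' deposited table (adjusted p = 2.56e-18), and Eif2ak3, which encodes PERK, by 0.33 (adjusted p = 0.0103), the latter chosen after its values were seen. With the ratios divided by their inflation factor, the call of Eif2ak3 ended (adjusted p = 0.209). Psat1 and Psph, of serine synthesis, had -0.75 and -0.56 in the authors' deposited table, and the mitochondrial folate enzyme gene Mthfd2 had -0.49. Of 26 secretory pathway genes of the IRE1-XBP1 branch 0 rose, 0 fell and 26 did not pass, with 0 and 0 adjusted over the list alone (median -0.11, adjusted p = 0.123), and 3 higher and 2 lower at an unadjusted p under 0.05. The smallest p-values there belonged to Sec61g, a translocon subunit gene with -0.70 (adjusted p = 0.111), and Sec11c, a signal peptidase gene with 0.29 (adjusted p = 0.156), in the authors' deposited table. Of 20 ER-associated degradation genes 1 rose, 2 fell and 17 did not pass, with 2 and 2 adjusted over the list alone (median 0.05, adjusted p = 0.993). Os9, a lectin gene, rose by 0.38 and the ubiquitin-conjugating enzyme gene Ube2j1 had -0.39 in the authors' deposited table, beside Herpud1.

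Secreted factors of senescent cells included 2 that rose in KO, Gdf15 and Lif. Of 23 measured members of the 44 on the list 2 rose, 1 fell and 20 did not pass, with 2 and 2 adjusted over the list alone, and the list did not pass the camera test (median 0.32, adjusted p = 0.123). Gdf15, a stress cytokine gene that is on the p53 list too, rose by 1.31 in the authors' deposited table (adjusted p = 1.67e-06). Lif, an interleukin-6 family cytokine gene, rose by 2.02 (interval 1.04 to 3.01) in the authors' deposited table, at a mean of 2.14 CPM (adjusted p = 0.00309). The adjusted p of Lif was 0.116 with the ratios divided by their inflation factor, which ended the call. Csf1, a macrophage growth factor gene, had -0.59 in the authors' deposited table (adjusted p = 0.0423). Of 16 genes of the LIF and STAT3 axis 1 rose (Lif), 1 fell and 14 did not pass, with 1 and 2 adjusted over the list alone (median -0.03, adjusted p = 0.372). The LIF receptor gene Lifr fell, with -0.67 in the authors' deposited table (adjusted p = 3.5e-12).

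Neither list of immune genes passed the camera test. Of 27 interferon response genes 0 rose, 0 fell and 27 did not pass, with 0 and 0 adjusted over the list alone (median -0.23, adjusted p = 0.131), and 0 higher and 4 lower at an unadjusted p under 0.05. Ddx60, an RNA helicase gene, had -0.71 (adjusted p = 0.0716) and Ifit3, an antiviral effector gene, -1.63 (adjusted p = 0.125) in the authors' deposited table. Of 19 MHC class I presentation genes 1 rose, 0 fell and 18 did not pass, with 1 and 0 adjusted over the list alone (median 0.12, adjusted p = 0.372). That gene was the peptide transporter Tap2, with a rise of 0.48 in the authors' deposited table (adjusted p = 0.0455).

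Among 29 proliferation genes 1 rose, 2 fell and 26 did not pass, with 1 and 3 adjusted over the list alone (median -0.20, camera adjusted p = 0.131). The cyclin gene Ccnd1 rose by 0.69 in the authors' deposited table, whereas Foxm1, a transcription factor of mitotic genes, had -1.42 and the topoisomerase gene Top2a -1.11. Oxidative phosphorylation genes were lower as a group, with 0 of 34 higher, 1 lower and 33 not passing, 0 and 1 adjusted over the list alone, and a median of -0.13 (adjusted p = 0.000436). Here too Sst, Pyy and Rbp4, 3 of the 9 measured delta and PP cell markers, were higher. With fold changes as the statistic the adjusted p of this list was 0.119, and with Fisher's exact test it was 1.0, which ended the call. Of 20 glycolysis genes 0 rose, 0 fell and 20 did not pass, with 0 and 0 adjusted over the list alone (adjusted p = 0.902), and 0 higher and 1 lower at an unadjusted p under 0.05. The median of that list was 0.00 and slightly positive, while its mean statistic and test pointed down. Pkm and Aldoc, glycolytic enzyme genes, had -0.34 and -0.61 in the authors' deposited table, with adjusted p-values of 0.297 and 0.323.

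Markers of delta and PP cells, the somatostatin and pancreatic polypeptide cells of the islet, included 3 of 9 measured genes that rose, with 0 that fell and 6 that did not pass, and 4 and 2 adjusted over the list alone. The list did not pass the camera test (median 0.76, adjusted p = 0.0897). Among its lower members, Casr had -0.35 and Rgs2 -0.66 in the authors' deposited table, both chosen after their values were seen. Neither passed over all genes. In the authors' deposited table the somatostatin gene Sst rose by 0.84 (mean 326 CPM, adjusted p = 5.05e-05), Pyy by 0.76 (mean 44.9 CPM) and Rbp4 by 0.86 (mean 11.1 CPM). The calls of Pyy and Rbp4 ended with the ratios divided by their inflation factor, at adjusted p-values of 0.334 and 0.38. Of 9 alpha cell markers 0 rose, 1 fell and 8 did not pass, with 2 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.902). The member that fell, Loxl2, a lysyl oxidase gene, had -0.84 in the authors' deposited table, and the glucagon gene Gcg, chosen after its values were seen, had 1.76 (interval 0.50 to 3.02, adjusted p = 0.0984).

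Duct cell markers numbered 10, of which 0 rose, 0 fell and 10 did not pass, with 0 and 0 adjusted over the list alone (median 0.25, adjusted p = 0.123), and 4 higher and 1 lower at an unadjusted p under 0.05. Ambp and Muc1 stood at 0.54 and 0.65 in the authors' deposited table, with adjusted p-values of 0.127 and 0.168. Schwann cell and neuron markers numbered 5, with 0 that rose, 0 that fell and 5 that did not pass, and 0 and 0 adjusted over the list alone (median 0.28, adjusted p = 0.372), and 0 and 0 at an unadjusted p under 0.05. The receptor gene Erbb3 stood at 0.38 in the authors' deposited table, with an adjusted p of 0.539. Of 23 dissociation and immediate early genes 0 rose, 0 fell and 23 did not pass, with 0 and 0 adjusted over the list alone (median 0.16, adjusted p = 0.108), and 4 higher and 0 lower at an unadjusted p under 0.05. Dnajb1, a heat shock gene, stood at 0.45 and Zfp36, an immediate early gene, at 0.55 in the authors' deposited table, with adjusted p-values of 0.0956 and 0.223.

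The remaining lists had fewer than 5 measured members and were not tested as groups. Of 3 acinar markers 1 rose, 0 fell and 2 did not pass, with 1 and 0 adjusted over the list alone, and the slightly negative median and the positive mean statistic differed in sign. Of 4 macrophage markers 0 rose, 1 fell and 3 did not pass, with 0 and 1 adjusted over the list alone, and the lysosomal protein gene Cd68 had -1.73 in the authors' deposited table (adjusted p = 0.00619). The lists of T and NK cells (3 measured), alternatively activated macrophages (3), endothelial cells (4), stellate cells and fibroblasts (4), B cells (1), red blood cells (1) and sex-specific genes (1) had 0 members that rose and 0 that fell, also adjusted over the list alone, and of their members only 1 endothelial gene was higher at an unadjusted p under 0.05. The authors' deposited table gives Cd247 and Lck of T cells as -0.93 and -0.49, and Stab1 and Lyve1 of macrophages as 0.55 and -0.18. Pecam1 and Vwf of endothelium stood at 1.06 and 1.14, and Col1a1 and Col3a1 of fibroblasts at 1.75 and -1.06, in the authors' deposited table. Cr2 of B cells and Alas2 of erythroid cells stood at 0.71 and 0.54 in the authors' deposited table. Xist, expressed from the inactive X chromosome, had 0.14 at a mean of 2180 CPM in the authors' deposited table (adjusted p = 0.815).

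**Figure D2:**
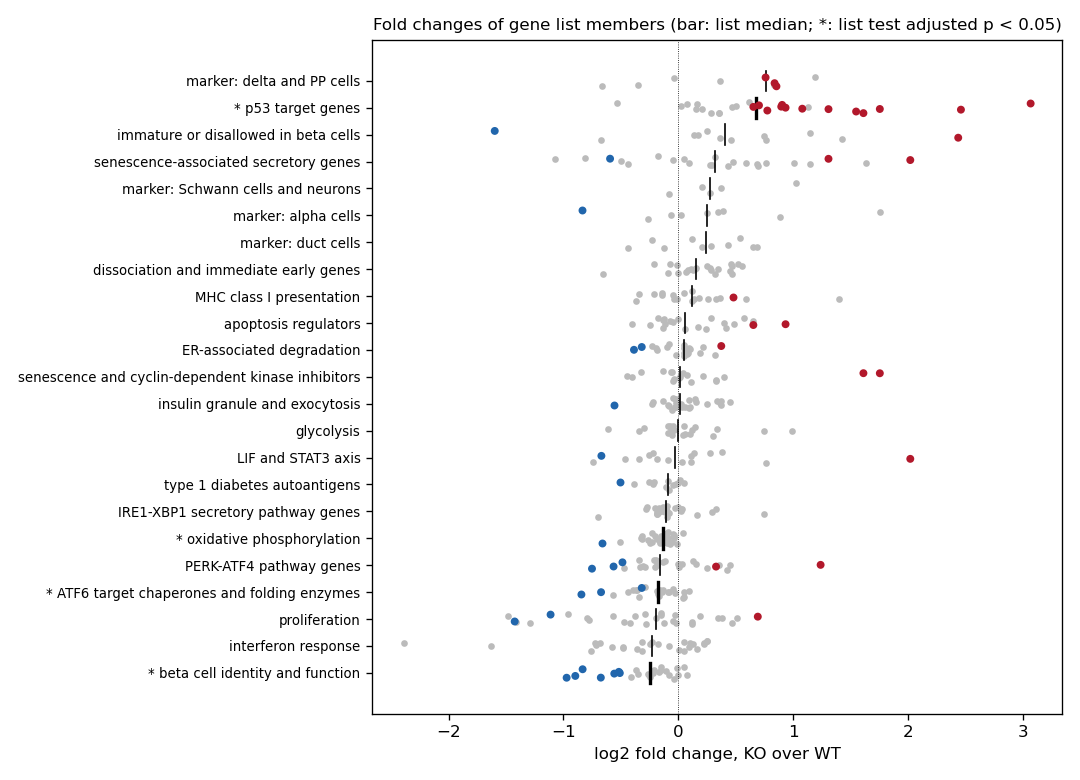
Log2 fold change of KO over WT (x axis) of each member of the 23 tested lists, from the authors' deposited table, with each list's median as a bar. Red and blue points are members higher and lower at an adjusted p under 0.05, grey points the rest, and an asterisk marks the 4 lists that passed the camera test: p53 targets with a median of 0.68, and oxidative phosphorylation, ATF6 targets and β cell identity with medians of -0.13, -0.17 and -0.24.

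The largest rise was that of Esr1, the estrogen receptor alpha gene, at 7.44 on the log2 scale in the authors' deposited table (interval 7.13 to 7.75, a 173-fold change, mean 68.7 CPM, adjusted p listed as 0). Esr1 lies on chromosome 10 at 4611593 to 5005614 (GRCm38), and part of it is carried by tamoxifen-inducible Cre transgenes, which the labels do not assign to a genotype. A transgene effect therefore cannot be told apart from the loss of Atf6 for any difference between KO and WT. Among genes that are not predicted genes and have a mean log2 CPM of at least 1, the largest rises in the authors' deposited table also included, beside Eda2r and Phlda3, those of the pseudogene Pabpc1l2a-ps with 4.95, Psrc1, a microtubule regulator gene, with 2.90, and the myosin gene Myo5c with 2.68. Inka2, a kinase inhibitor gene, rose by 2.55, Serpinb1a, a protease inhibitor gene, by 2.39 and Col18a1, a basement membrane collagen gene, by 2.28 in the authors' deposited table. Among the falls under the same limits, AY036118, a transcript of the ribosomal RNA region, is listed at -17.31 in the authors' deposited table, a fitted value that cannot be read as a fold. Other large falls under these limits in the authors' deposited table were AA474408 with -2.20, the mitochondrial glycine tRNA gene mt-Tg with -2.19, the ribosomal RNA gene n-R5-8s1 with -2.18, and the microRNA genes Mir6240 and Mir6236 with -2.09 and -2.03. Myh7b, a myosin gene, stood at -1.99, Tmigd3 at -1.79 and Stmn1, the stathmin gene, at -1.72 in the authors' deposited table, beside Cd68. With the ratios divided by their inflation factor, the calls of Pabpc1l2a-ps, Serpinb1a, n-R5-8s1, mt-Tg, Mir6240, Myh7b, Stmn1 and Cd68 ended, as did those of Psph, Ube2j1, Os9, Csf1, Tap2, Ccnd1, Foxm1 and Top2a on the lists above.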

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

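Of the alternatives, the 2-fold minimum was planned, and the others were chosen after seeing the data. No paired analysis was possible because the authors' deposited table has 1 value per gene for both groups. For the same reason leaving out replicates, other splits of the samples, other scalings and tests, a batch term, an estimated correlation and fry were not run, and depth per sample is unknown. The 698 changed genes (394 higher, 304 lower) became 209 (151 and 58) at a 2-fold minimum, 199 (115 and 84) with ratios divided by the inflation factor and 401 (233 and 168) at an adjusted p under 0.01, each a stricter rule by construction, and between 695 and 701 under the other settings. Atf6 kept its call under all 5. The 83 genes named by the rule include some that were not called changed and had no call to lose. Among the 83, 24 lost their call under the inflation factor, 14 at an adjusted p under 0.01 and 25 at the 2-fold minimum. Of the list results under alternative settings, 126 stayed on the same side of the threshold, 8 gained a call, 4 lost it and 0 reversed. Most of these results belong to lists without a call in the main test (adjusted p-values follow in brackets). With fold changes as the statistic, calls ended for ATF6 targets (0.0716) and oxidative phosphorylation (0.119) and arose for immature genes (0.0457), secreted factors (0.0494), interferon (0.0122) and proliferation (0.00992). With ranks they arose for IRE1-XBP1 (0.0497) and dissociation (0.0347). With Fisher's exact test they ended for ATF6 targets (0.271) and oxidative phosphorylation (1.0) and arose for PERK-ATF4 (0.0386) and delta and PP markers (0.0386). The cause was not tested.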

Other observations

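The tests on Esr1 as a transgene, on p53 targets above the delta and PP markers, on a lower share of β cells, and the 3 added lists were chosen only after results had been seen. The other tests below were written before their results, on patterns already seen, and genes named here were chosen after their values were seen.

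Of the changed genes on none of the fixed lists, the following stand among those with the smallest p-values and were not tested as a group. In the authors' deposited table, Ly6e, a surface protein gene, rose by 1.39 on the log2 scale (adjusted p = 2.06e-43), the hyaluronan receptor gene Cd44 by 1.04, the tetraspanin gene Cd81 by 0.87, the heparan sulfatase gene Sulf2 by 1.91 and the membrane protease gene St14 by 0.99. The stress kinase gene Map3k20 rose by 1.60, Trp53i11, named for its induction by p53, by 0.87 and the antioxidant enzyme gene Gpx3 by 1.14 in the authors' deposited table. Cntfr, a receptor subunit gene for ciliary neurotrophic factor, fell, with -1.21 in the authors' deposited table (adjusted p = 3.88e-12). Ciliary neurotrophic factor signals through the receptor encoded by Lifr, which had -0.67 in the authors' deposited table. Ppp1r1a, a protein phosphatase inhibitor gene abundant in β cells, had -1.10, Cbs, of cysteine synthesis, -0.80 and the lipoprotein lipase gene Lpl -0.79 in the authors' deposited table.

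Changed genes of small or repeat RNA types were lower without exception, with 0 higher and 5 lower among microRNA genes and 0 higher and 1 lower each among genes of ribosomal RNA, mitochondrial transfer RNA, small nuclear RNA and miscellaneous RNA. On the added list of ribosomal RNA repeat loci, 0 of 7 rose, 2 fell and 5 did not pass, with 0 and 3 adjusted over the list alone (median -0.25, camera adjusted p = 0.00182 over the 3 added lists), but the list was drawn up after AY036118, a member, had been seen. Without AY036118, an alternative chosen after seeing the data, 0 of 6 rose, 1 fell and 5 did not pass, and the list did not pass the test (median -0.18, camera adjusted p = 0.0664). The remaining gene that fell, Lars2, whose annotated gene holds a sequence resembling ribosomal RNA, had -1.26 in the authors' deposited table (mean 2568 CPM, adjusted p = 0.0161), a call that ended with the ratios divided by their inflation factor (adjusted p = 0.259).

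The other added lists concern signalling through the estrogen receptor and through the growth hormone that some Cre transgenes encode. Of 10 measured estrogen receptor targets 2 rose (Ccnd1 and Ctsd), 0 fell and 8 did not pass, with 3 and 0 adjusted over the list alone. Their median of 0.24 had an interval from -0.08 to 0.56 (camera adjusted p = 0.0649 over the 3 added lists), and the unadjusted p lay under the level of 0.05 set beforehand while the count of raised genes stayed under the 3 set with it, which leaves active receptor signalling open. With the ratios divided by their inflation factor, the calls of Ccnd1 and Ctsd ended (adjusted p = 0.118 and 0.26). On the added list of growth hormone and prolactin targets, 0 of 14 rose, 2 fell and 12 did not pass, with 1 and 2 adjusted over the list alone (median -0.02, adjusted p = 0.219). The test of expressed growth hormone was set on Tph1, Cish and Socs2, genes raised by it, of which Tph1 was not analysed here. The higher upper bound of Cish and Socs2 was 0.38, under the bound of 1 set beforehand, which argues against a strong response in these 2 genes.

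The rise of p53 targets coincided with the 7.44 log2 rise of Esr1, whose ligand-binding part tamoxifen-inducible Cre transgenes carry. The strongest targets were set against Sst, Pyy and Rbp4, the raised delta and PP markers. Of 26 members, 5 (Cdkn1a, Ccng1, Eda2r, Phlda3 and Tnfrsf10b) had lower bounds above 1.06, the upper bound of the pooled rise of these markers (0.82). These pooled values argue against delta cells as the source of the 5 targets. Ppy, the pancreatic polypeptide gene, had 1.19 in the authors' deposited table (adjusted p = 0.152) and was outside that pool. PP cells therefore stay open for these 5 targets, as do alpha, endothelial and other cells, over whose markers the bound was not pooled. For the remaining members delta and PP cells stay open as well. The median of the delta and PP list, 0.76, reached the p53 list median of 0.68, the level set beforehand. Its bootstrap interval ran from -0.35 to 1.03, and that interval was added to the rule after the value was seen. Isolation stress stays open too, since 22 dissociation genes had a median of 0.15 with an upper bound of 0.35, against the 0.34 set as the bound. A Cre transgene in KO mice, with tamoxifen given to both groups, may itself raise p53 targets through DNA breaks. It cannot be told apart from the loss of Atf6, because no group is known from the labels to carry the transgene with intact Atf6. The same holds for every other difference between KO and WT, among them the identity, ATF6 target and oxidative phosphorylation lists and Lif.

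Lower expression of β cell identity genes could come from a lower share of β cells in the KO sorts, which would lower genes restricted to β cells alike. The log2 fold changes of 8 such genes, from -0.97 for Slc2a2 to -0.08 for Ins1 in the authors' deposited table, differed among themselves (chi-square test of heterogeneity, p = 0.000147). With the ratios divided by their inflation factor the p of this chi-square test was 0.0182, and it was 0.0994 without G6pc2 and 0.0685 without Slc2a2, so a lower share stays open. A change of identity within KO β cells, as a biological explanation, was not tested. Nor can an effect of a Cre transgene in KO mice be told apart from the loss of Atf6 for these genes.

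Fh1, the fumarate hydratase gene, had -1.61 in the authors' deposited table (adjusted p = 2.74e-36) and lies on chromosome 1 at 175600374 to 175625635, near Atf6. A strain haplotype around the targeted locus could lower such neighbors in KO only if it differed between the groups. WT mice were Atf6fl/fl, so they carried the targeted locus as well. Of 165 genes within 10 Mb of Atf6, 8 changed (4.85%), against 689 of 15790 elsewhere (4.36%), an odds ratio of 1.12 (95% interval 0.47 to 2.27, Fisher's exact test, two-sided, p = 0.701), which leaves an effect on single neighbors open. Wider strain differences could cluster changed genes. Of 262 windows of 10 Mb, the one with the largest excess of changed genes for its gene count was on chromosome 6, with 10 of 95 genes changed. It had no larger an excess than shuffled calls often give (permutation p = 0.846). Strain differences that do not gather changed genes within such windows would escape this test and stay open. An effect of Atf6 loss on Fh1 was not tested.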
